A study of Mus musculus with 12 samples.

How the data were processed

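Liver RNA was measured on Affymetrix 3′ expression arrays, 1 array per mouse, in 12 male C57BL6J mice at 30 weeks of age. Per the labels, the mice fall into 4 groups of 3, control or low-dose penicillin crossed with chow or high-fat diet, and the labels call the 3 samples of a group biological replicates. Per the labels' protocols, total RNA was purified with a column kit and hybridised as a biotin-labelled copy. Scan date, hybridisation batch, cage and litter were not used here, so a batch that follows a group was not tested.

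The authors deposited 1 table of log2 expression values for 45101 probe sets on 12 arrays, made with RMA in the affy package per the submitters' processing notes, whose versions are not given in the sources used here. RMA corrects background, gives every array the same distribution of probe intensities and combines the probes of a set into 1 log2 value. The deposited log2 values had array medians between 5.52 and 5.59, and none was missing. RMA removes any overall difference in the amount of RNA between arrays, so every change below is relative to the bulk of the genes. Detection calls were not used here: values near the dim end of the table cannot be told from background, and the fold change of a gene that is dim in 1 group is compressed.

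Probe sets were named from GEO's platform annotation. Of the probe sets, 34945 had 1 gene symbol, 932 had several, 9160 had none and 64 were control probe sets. The gene IDs of 34741 probe sets were found in a gene table of assembly GRCm38.p6, which changed 0 symbols. For each of 18193 genes the probe set with the highest mean over all arrays was kept. Genes above the 40th percentile of all values (log2 5.00) on at least 3 of the 12 arrays were tested, which left 13788 genes, 7912 of them with more than 1 probe set. Probe sets of several genes were not used here.

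Differences were tested with limma (version 3.58.1, in R 4.3.3): lmFit with 4 group means on all 12 arrays, which leaves 8 residual degrees of freedom, then eBayes and the Benjamini-Hochberg adjustment over the 13788 genes, at an adjusted p under 0.05. The 7 contrasts were penicillin within each diet, diet within each treatment, their interaction, and both effects averaged. The labels call the replicates biological, and the p-values measure the spread between these mice. Array data give no read depth, and the number of arrays limits the precision: the median standard error was 0.10 for a contrast between groups and 0.15 for the interaction, and the median within-group SD was 0.13. The rule for named genes takes, per contrast, the 10 higher and 10 lower genes with the largest change among those past the threshold whose groups do not overlap. Where fewer than 10 genes pass, it takes all of them and the 10 with the smallest p, and it adds up to 4 members of each described list with the smallest p. A gene named in 1 contrast may be followed in others. Chance alone keeps groups of 3 mice from overlapping for 10% of genes.

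Before the data were examined, 36 gene lists were fixed for lipid, sterol, carbohydrate, amino acid and xenobiotic metabolism, sex-biased liver genes, inflammation and stress, the clock, cell division, and markers of the cell types a liver sample can hold. The 35 lists with at least 5 tested members were tested with limma's camera at its preset correlation of 0.01, adjusted by Benjamini-Hochberg over the lists. The same lists were tested with camera at an estimated correlation, which allows for genes of a list that vary together between mice, and with fry, which asks whether a list's genes move on balance in 1 direction. Members are counted as higher or lower after adjustment over all genes, and again adjusted over the list alone.

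The pipeline was tested on simulated data for penicillin on high-fat diet over 13788 genes. Each size of change was given to 50 genes. The pipeline recovered 58% of genes changed by 0.5 log2 units, 96% of those changed by 1 and 100% of those changed by 2 or 3. There were 4 false calls among 181. Contrasts with far fewer calls face a stricter threshold, and the interaction has a larger standard error, so these shares do not carry over to them. With independent genes and no list moved, 0 of 245 list tests passed. Array measures were compared with two-sided exact permutation tests over 924 splits of 6 against 6 arrays, 24 tests in all, adjusted by Benjamini-Hochberg. Alternatives covered the filter, the choice of probe set, cyclic loess, median centring, array weights, eBayes with trend and robust variance, only the 6 arrays compared, a replicate block, the thresholds and leaving out each array in turn. After the arrays had been examined, fits with the 18S signal or a clock score as a covariate were added, as were fits without 3 arrays of low 18S signal and without 2 outlying arrays.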

Results

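Livers of 12 male C57BL6J mice, a common inbred laboratory strain, were profiled at 30 weeks of age on 3′ expression arrays. Mice drank plain water or water with penicillin at 6.7 mg/L, a dose far below treatment level. All began on chow with 13.5% of energy as fat, and some were moved at 17 weeks to a high-fat diet with 45%. The 4 groups of 3 mice are called control chow, penicillin chow, control high-fat and penicillin high-fat, and single arrays carry the replicate number, as in control chow 1. The design asks whether low-dose penicillin alters hepatic gene expression on either diet, whether high-fat feeding does so in either kind of mouse, and whether these effects depend on each other. Changes are differences of group means of log2 expression, given with the standard error of the fit, for n = 3 mice per group. Adjusted p-values come from limma with the Benjamini-Hochberg procedure.

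All 12 arrays matched the label male, with Xist between 4.37 and 4.69 and the Y-linked gene Eif2s3y between 9.37 and 9.90. Arrays of a group correlated at 0.985 to 0.995. The first principal component held 36.3% of the variance and separated the diets, from -16.2 to -12.5 on chow and from 3.01 to 25.7 on high-fat diet. The second component, 15.4%, set penicillin chow 1 apart, at -30.1 against -5.32 to 10.6 for the other arrays. That mouse had high acute-phase genes: 21 of 26 measured lay above the range of the other 11 arrays, with Saa1 at 13.8 against at most 11.9 and Lcn2 3.56 above the mean of the others. The 18S control signal was low in penicillin chow 2 and 3 and penicillin high-fat 2, at 11.5, 11.5 and 11.6 against at least 12.7 elsewhere. A clock score, the mean of Per and Dbp phase genes minus that of Bmal1 phase genes, was lowest in penicillin high-fat 1, at -1.57, with the other arrays between -0.77 and 0.73.

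**Figure D1:**
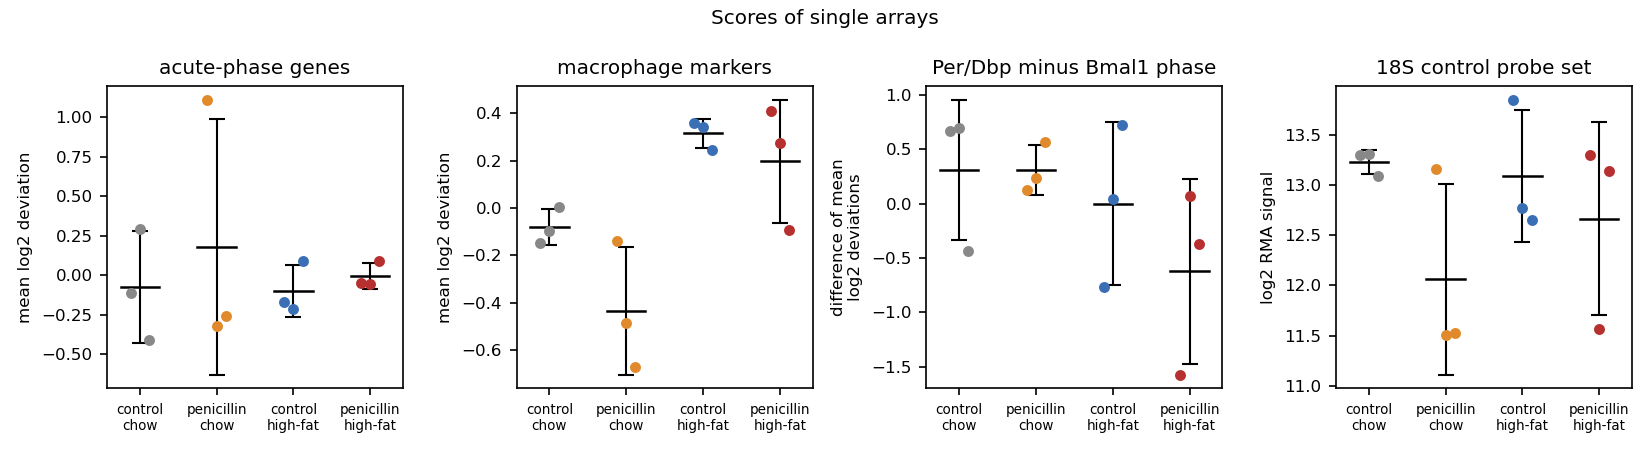
Scores of the 12 arrays by group: the acute-phase and macrophage scores are mean log2 deviations of the listed genes from their mean over all arrays, the clock score is a difference of such means, and the last panel is the log2 signal of the 18S control probe set. Points are mice, horizontal lines means and bars SD (n = 3); penicillin chow 1 stands at 1.11 on the acute-phase score and penicillin high-fat 1 at -1.57 on the clock score.

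Penicillin was first compared with control in mice on chow. Rcan2, which encodes a regulator of the phosphatase calcineurin, rose by 0.85 ± 0.10, from 6.09 to 6.94 (1.80-fold; adjusted p = 0.0470), and its 3 penicillin mice all lay above the 3 controls. It was the 1 gene of 13788 past the threshold, and 1051 genes had an unadjusted p under 0.05 where chance gives 689.4. The interferon-inducible gene Ifi27l2a missed the threshold at -0.68 ± 0.09 (adjusted p = 0.0583). B3galnt1 at -0.96 ± 0.14, the endothelial genes Clec14a at -0.76 ± 0.12 and Sox18 at -0.43 ± 0.08, Gucy1a1 at -0.69 ± 0.11, Ccdc162 at -0.69 ± 0.12, the purinergic receptor P2ry14 at -0.58 ± 0.11, the inflammasome adaptor Pycard at -0.50 ± 0.08 and Zeb2 at -0.46 ± 0.08 did not pass either, with adjusted p from 0.116 to 0.190. A further probe set of Gucy1a1 stood at 0.10 and one of Clec14a at -0.37.

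Several lists of non-parenchymal genes lay lower in penicillin mice on chow, with no member past the threshold over all genes. Macrophage and Kupffer cell markers had a median of -0.40 over 21 genes, 19 of them negative. Mpeg1 stood at -0.58 ± 0.14 and the complement receptor Vsig4 at -0.53 ± 0.17. Camera gave an adjusted p of 1.67e-08, against an adjusted p = 0.429 with an estimated correlation, and 1 gene was lower adjusted over the list alone. The MHC class II list had a median of -0.40 over 8 genes (adjusted p = 3.06e-05, and adjusted p = 0.349 with an estimated correlation), with 0 called adjusted over the list alone. Sinusoidal endothelial markers had a median of -0.19 over 15 genes, with Oit3 at -0.34 ± 0.10 and Stab2 at -0.33 ± 0.11, and 4 were lower adjusted over the list alone (adjusted p = 6.91e-06, and adjusted p = 0.349 with an estimated correlation). The stellate cell and fibrosis list had a median of -0.11 over 22 genes, with Col3a1 at -0.58 ± 0.17 (adjusted p = 0.00240, and adjusted p = 0.660 with an estimated correlation), and 0 were called adjusted over the list alone. The 2 penicillin mice with the lowest macrophage scores on chow, at -0.49 and -0.67, were also those with a low 18S signal. The other low-18S array, penicillin high-fat 2, did not follow this. Its macrophage score was 0.28, against 0.41 and -0.09 in penicillin high-fat 1 and 3.

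Heat shock genes lay higher on chow, with a median of 0.50 over 10 genes, all positive. Hspb1 stood at 1.12 ± 0.31 and the chaperone Hsp90aa1 at 0.48 ± 0.14, and 2 were higher adjusted over the list alone. Camera gave an adjusted p of 1.45e-05, against an adjusted p = 0.349 with an estimated correlation. The acute-phase list had a median of 0.12 over 26 genes (adjusted p = 0.00691, and adjusted p = 0.935 with an estimated correlation), its score stood at 1.11 in penicillin chow 1 against -0.32 and -0.26 in the other mice of the group, and without that mouse the direction turned (list acute phase: penicillin on chow, adjusted p = 0.265). Of 35 lists 11 passed camera on chow, or 7 without penicillin chow 2, 0 with the estimated correlation and 0 with fry. The count of genes was 0 without control chow 1 or 2, penicillin chow 2 or 3, control high-fat 2 or any 1 of the penicillin high-fat mice, 2 without penicillin chow 1 and 4 without control chow 3. Rcan2 kept its call in 3 of the 12 fits that left out an array.

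On high-fat diet, penicillin raised 5 of 20 lipid droplet and PPAR gamma target genes and lowered 3 of 11 genes that are higher in male than in female liver. Cidea and Cidec, which encode proteins that enlarge lipid droplets, rose by 3.70 ± 0.38 (from 5.52 to 9.22; adjusted p = 0.00154) and 2.96 ± 0.39 (from 5.55 to 8.51; adjusted p = 0.00841). Mogat1, an acyltransferase of diacylglycerol synthesis, rose by 1.60 ± 0.21, the fatty acid transporter Cd36 by 1.24 ± 0.11 and the lipoprotein receptor Vldlr by 1.29. Hsd3b5, a steroid-metabolising enzyme of male mouse liver, fell by 3.83 ± 0.50, from 12.39 to 8.56 (adjusted p = 0.00739). In all, 47 genes changed, 35 higher and 12 lower, and 39 of them by at least 1.5-fold.

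Of 20 measured lipid droplet and PPAR gamma target genes, 5 rose on high-fat diet under penicillin and 0 fell over all genes, while 10 were higher and 1 lower adjusted over the list alone. The list had a median of 0.30 and passed camera (adjusted p = 6.61e-09), also at adjusted p = 0.00465 with an estimated correlation and under fry (adjusted p = 3.43e-05). The receptor Pparg itself, at 0.79, and the droplet protein Plin2, at 0.40, did not pass, with adjusted p of 0.388 and 0.430. Adipocyte markers, a list of 7 genes that shares Cidec, Fabp4, Lipe and Lpl with this one, had a median of 0.03, with Fabp4 at 0.27 ± 0.23 and Pck1 at -0.15 ± 0.22.

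Of 11 male-biased liver genes, 3 fell over all genes and 7 adjusted over the list alone: Hsd3b5, the oxysterol hydroxylase Cyp7b1 by 0.79 ± 0.11 and the organic anion transporter Slco1a1 by 0.84 ± 0.12, with Susd4 at -0.95 ± 0.19 (adjusted p = 0.0751). The list median was -0.41; camera gave an adjusted p of 4.41e-08, fry 0.00687, and camera adjusted p = 0.105 with an estimated correlation. Among 15 female-biased genes, 1 rose, the peroxisomal hydroxyacid oxidase Hao2, by 1.56 ± 0.15 (1 adjusted over the list alone), and the list did not pass camera (adjusted p = 0.0530). The clock score was low in penicillin high-fat 1. Per and Dbp phase genes had a median of -0.37 over 13 genes, with 0 called over all genes or the list alone and Dbp at -1.07 ± 0.58 (adjusted p = 0.00414, and adjusted p = 0.444 with an estimated correlation).

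NRF2 targets, genes of the antioxidant response, were all 13 positive under penicillin on high-fat diet, with a median of 0.48. The detoxifying enzymes Gstm3 and Nqo1 rose by 1.44 ± 0.19 and 0.84 ± 0.12, and 9 members were higher adjusted over the list alone (camera adjusted p = 6.33e-10, fry adjusted p = 0.0253, and adjusted p = 0.183 with an estimated correlation). Cell cycle genes had a median of 0.22 over 16 genes, with 0 called over all genes, 5 higher adjusted over the list alone and Mcm2 at 0.45 ± 0.10 (adjusted p = 4.40e-06, fry adjusted p = 0.0232, and adjusted p = 0.129 with an estimated correlation). The stellate cell and fibrosis list had a median of 0.25 over 22 genes, 1 of them higher adjusted over the list alone, with Col3a1 at 0.88 ± 0.17 (adjusted p = 2.91e-04, and adjusted p = 0.327 with an estimated correlation). Hepatocyte markers had a median of -0.06 over 15 genes and passed fry (adjusted p = 0.00687) but not camera (adjusted p = 0.0671), with Cps1 at -0.33 ± 0.08 and 1 gene lower adjusted over the list alone.

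Other genes that rose under penicillin on high-fat diet were the organic anion transporter family members Slc22a27 by 2.06 ± 0.17 and Slc22a29 by 1.92 ± 0.25, the glycogen-targeting phosphatase subunit Ppp1r3g by 2.20 ± 0.40, the oxysterol-binding protein gene Osbpl3 by 1.62 ± 0.26, Wfdc2 by 1.58 ± 0.22 and the probe set of Rad51b by 2.94 ± 0.44. Rcan2 rose by 1.29, as it had on chow. Genes that fell were the elastase Cela1 by 1.33 ± 0.16, the cytokine receptor Lifr by 1.04 ± 0.12, Cyp4f14 by 0.62 ± 0.10, the peroxisomal aminotransferase Agxt by 0.61 ± 0.11, Cyp1a2 by 0.49 ± 0.09 and the apolipoprotein Apom by 0.48 ± 0.08. The complement component C8b fell as well (adjusted p = 0.0119). The other probe sets of Lifr stood at -0.67 and -0.55. Cela1 was the 1 called gene among 8 pancreatic acinar markers. The count of 47 was 22, 24 and 24 without control high-fat 1, 2 or 3, 21, 113 and 30 without penicillin high-fat 1, 2 or 3, and 95 without penicillin chow 1. It was 98 with the 18S signal as a covariate. Of the 20 genes named by size, 11 passed in each of the 12 fits that left out an array: Cidea, Cidec, Mogat1, Slc22a27, Slc22a29, Hao2, Wfdc2, Hsd3b5, Lifr, Cyp7b1 and Cela1.

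The interaction asks whether the effect of penicillin on high-fat diet differed from that on chow. It was positive for Cidea at 3.80 ± 0.53, Hao2 at 2.06 ± 0.22, the organic anion transporter gene Slc22a27 at 1.66 ± 0.24, Cd36 at 1.21 ± 0.15 and Ifi27l2a at 0.97 ± 0.13, and negative for Lifr at -1.22 ± 0.16, whose other probe sets stood at -0.72 and -0.28. These were the 6 genes past the threshold, with adjusted p from 0.0114 to 0.0418. Cd36 showed no detectable penicillin effect on chow, at 0.03 (adjusted p = 0.971), against a rise of 1.24 on high-fat diet. For Ifi27l2a the chow value was -0.68. Cidea, Hao2 and Slc22a27 lay near the floor of the filter in both chow groups, so their penicillin effect on chow was not measurable and their interaction does not show that the effects differ. Hsd3b5, at -3.43 ± 0.70, and Mogat1, at 1.43 ± 0.29, did not pass (adjusted p = 0.192 and 0.190), so their penicillin effects are not shown to differ between diets. The same holds for Pigp at 0.81 ± 0.12, Sox18 at 0.64 ± 0.11, Enc1 at 1.04 ± 0.18 and Col3a1 at 1.47 ± 0.25, with adjusted p from 0.0660 to 0.108.

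**Figure D2:**
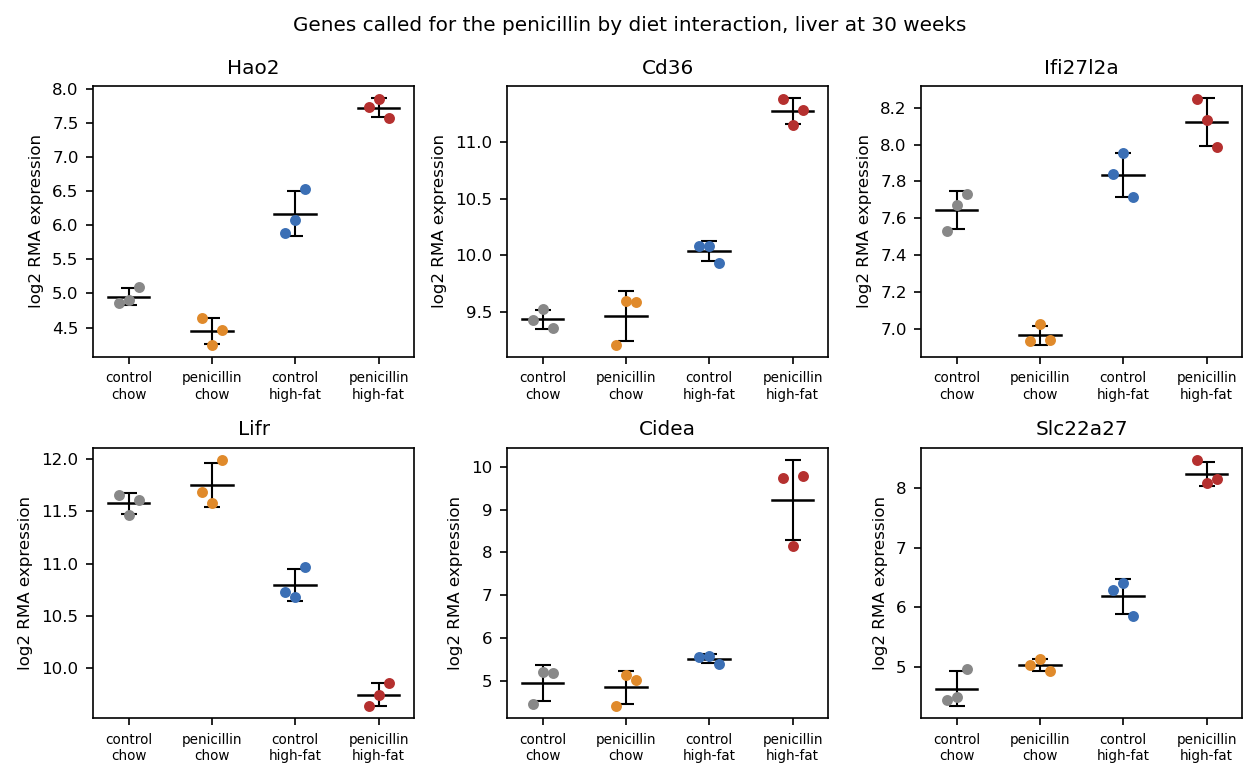
Log2 expression in single mice of the 6 genes called for the interaction, by group. Points are mice, horizontal lines means and bars SD (n = 3); Cidea lay between 8.14 and 9.79 in penicillin mice on high-fat diet and at most 5.59 in each mouse of the other groups.

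The lipid droplet and PPAR gamma target list had a median interaction of 0.49 over 20 genes, 18 of them positive, with 2 higher over all genes and 7 higher and 1 lower adjusted over the list alone. It passed camera (adjusted p = 3.24e-08), also at adjusted p = 0.00545 with an estimated correlation. In all, 18 lists passed camera, 1 with the estimated correlation and 3 with fry. The count of 6 genes fell to 0 without control chow 2, penicillin chow 3 or penicillin high-fat 1. It was 1 without control high-fat 1 or 3 or penicillin high-fat 3, 3 without penicillin chow 1 or 2, and 10 without control chow 3. With the 18S signal or the clock score as a covariate it was 2. When arrays were regrouped at random inside each diet, 9 of 100 splits, the real one included, called at least as many genes. None of the 6 genes passed in all 12 such fits; Hao2 did in 9, Cd36 in 6, Lifr in 4, Ifi27l2a and Slc22a27 in 3 and Cidea in 2.

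Averaged over the diets, penicillin changed 20 genes, 14 higher and 6 lower. Rcan2 rose by 1.07 ± 0.07 (adjusted p = 9.96e-05), higher in all 3 penicillin mice than in all 3 controls on both diets. Cidec rose by 2.05 ± 0.28, Wfdc2 by 1.08 ± 0.15, the acylphosphatase gene Acyp2 by 0.84 ± 0.13, Comtd1 by 0.54 ± 0.09, Plekha1 by 0.50 ± 0.08 and Secisbp2l by 0.31 ± 0.05. The nuclear noncoding RNA Malat1 fell by 0.63 ± 0.09 and B3galnt1 by 0.62 ± 0.10. Other probe sets of Malat1 ranged from -0.54 to -0.23, and that of Secisbp2l stood at 0.05. Of the male-biased genes, Hsd3b5, Slco1a1 and Cyp7b1 fell by 2.12 ± 0.35, 0.50 ± 0.08 and 0.49 ± 0.08. On chow Hsd3b5 stood at 11.70 in penicillin chow 1. It was 12.88 and 12.87 in penicillin chow 2 and 3, within the control range of 12.68 to 13.01. Cyp7b1 overlapped on chow, at 13.37 to 13.51 in penicillin and 13.41 to 13.83 in control mice. The averages of Hsd3b5 and Cyp7b1 thus do not show a fall on chow. Slco1a1 was not called on chow, so its average does not show a fall there either. Cidea, Mogat1 and Cd36 rose by 1.80 ± 0.27, 0.89 ± 0.15 and 0.63 ± 0.08. Cd36 passed the interaction test, so its average is not read as an effect common to both diets, and Cidea was not measurable on chow. Mogat1 overlapped on chow, at 5.65 to 6.31 in penicillin and 5.77 to 6.01 in control mice. Its average thus does not show a rise on chow. Cidec lay at 4.73 to 4.83 in control mice on chow, below the floor of the filter. It stood at 7.04 in penicillin chow 1, the mouse with high acute-phase genes, and at 5.22 and 5.51 in penicillin chow 2 and 3. The average of Cidec is thus not read as an effect common to both diets either.

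The lipid droplet and PPAR gamma target list, with 4 of 20 genes higher, or 7 adjusted over the list alone, had a median of 0.15 (adjusted p = 7.75e-05, and adjusted p = 0.0477 with an estimated correlation). NRF2 targets had a median of 0.30, 0 called over all genes and 10 of 13 higher adjusted over the list alone (adjusted p = 1.29e-08, and adjusted p = 0.330 with an estimated correlation). Macrophage markers had a median of -0.30, with 0 called over all genes or the list alone (adjusted p = 1.61e-06, and adjusted p = 0.436 with an estimated correlation). The 18S signal was 0.80 lower in penicillin mice (exact permutation p = 0.0996, adjusted p = 0.312). The count of 20 was 3, 3, 4, 7, 5, 4, 2, 10 and 5 without control chow 1 or 2, penicillin chow 2 or 3, control high-fat 1, 2 or 3, and penicillin high-fat 1 or 3, and 93 without penicillin high-fat 2. With the 18S signal as a covariate it was 246. Rcan2 passed in each of the 12 fits that left out an array, and the other 8 genes named by size did not.

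Across all 13788 genes the penicillin effects on chow and on high-fat diet correlated at r = 0.219 (Spearman rho = 0.209), a correlation across genes, which are not independent replicates. The comparisons use different mice but come from 1 fit with a shared residual variance, so their lists of calls are not independent. Rcan2 was the 1 gene called higher on both diets, and 0 genes were shared lower.

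The diet comparison in control mice asks what high-fat feeding alone altered. The phosphatidate phosphatase Lpin1 rose by 2.01 ± 0.38, the acyl-CoA thioesterase Acot3 by 2.55 ± 0.48 and the apolipoprotein Apoa4 by 2.14 ± 0.43. The female-biased cytochrome genes Cyp2b9 and Cyp17a1 rose as well, Cyp2b9 by 3.50 ± 0.51 (from 6.03 to 9.52; adjusted p = 0.0127) and Cyp17a1 by 2.14 ± 0.26 (adjusted p = 0.00501). Of 31 xenobiotic metabolism genes 5 fell and 1 rose, and the list had adjusted p = 0.0654 with an estimated correlation. Among those that fell were Cyp1a2 at -1.19 ± 0.09 (adjusted p = 2.13e-04), the glutathione transferases Gsta2 at -1.85 ± 0.24 and Gstm3 at -1.71 ± 0.19, and Cyp2b10 at -1.77 ± 0.22. In all, 124 genes changed, 90 higher and 34 lower, 85 of them by at least 1.5-fold.

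Among 15 female-biased genes 4 rose in control mice on high-fat diet, Cyp2b9, Cyp17a1, Acot3 and Hao2 (1.22 ± 0.15), and 9 were higher and 1 lower adjusted over the list alone. The list median was 0.90 (camera adjusted p = 3.83e-05, and adjusted p = 0.0425 with an estimated correlation). Of 11 male-biased genes, Cyp7b1 fell by 0.86 ± 0.11 and 5 were lower adjusted over the list alone, with a median of -0.49 (adjusted p = 3.09e-06, fry adjusted p = 0.00695, and adjusted p = 0.0922 with an estimated correlation). In the glucose metabolism and insulin signalling list the fructose kinase gene Khk rose by 0.54 ± 0.07 and pyruvate carboxylase, Pcx, by 0.43 ± 0.07. They were 2 of 20 genes called, with 8 higher and 1 lower adjusted over the list alone. The median was 0.24 (adjusted p = 7.90e-07, and adjusted p = 0.0287 with an estimated correlation). The lipid droplet list had 3 of 20 genes higher, Cd36 by 0.60 ± 0.11, Vldlr by 1.15 ± 0.24 and the monoglyceride lipase Mgll by 0.54 ± 0.11, and 6 higher and 1 lower adjusted over the list alone, with a median of 0.21 (adjusted p = 6.35e-04, and adjusted p = 0.0425 with an estimated correlation).

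Of the xenobiotic metabolism genes in control mice, 17 were lower and 2 higher on high-fat diet adjusted over the list alone, with a median of -0.37 (adjusted p = 2.96e-11, fry adjusted p = 0.00187, and adjusted p = 0.0654 with an estimated correlation). Of 29 PPAR alpha and fatty acid oxidation genes 3 rose, Acot3, the pantetheinase Vnn1 by 1.61 ± 0.27 and Acot4 by 1.03 ± 0.20, or 9 adjusted over the list alone, with a median of 0.19 (adjusted p = 2.27e-08, fry adjusted p = 0.0105, and adjusted p = 0.121 with an estimated correlation). The desaturases Fads1 and Fads2 rose by 0.65 ± 0.11 and 0.77 ± 0.15 and the elongase Elovl5 by 0.85 ± 0.15. With Lpin1 they were the 4 of 24 fatty acid and triglyceride synthesis genes called, or 8 adjusted over the list alone (median 0.36, adjusted p = 3.45e-05, and adjusted p = 0.338 with an estimated correlation). Macrophage markers had a median of 0.50, 0 of 21 over all genes and 7 higher adjusted over the list alone (adjusted p = 2.55e-06, and adjusted p = 0.338 with an estimated correlation). Heat shock genes had a median of 0.73. Hsph1 rose by 1.16 ± 0.23, the 1 of 10 called, or 5 adjusted over the list alone (adjusted p = 4.09e-05, and adjusted p = 0.257 with an estimated correlation).

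Other genes that rose in control mice were the magnesium transporter family gene Nipal1 by 2.72 ± 0.42, the signalling regulator Rgs16 by 2.29 ± 0.41, the transcription factor Zbtb16 by 1.96 ± 0.32, 1810053B23Rik by 1.96 ± 0.25 and the water channel Aqp4 by 1.83 ± 0.38, whose other probe sets ranged from -0.01 to 0.92. Those of Zbtb16 ranged from 0.63 to 2.33. Genes that fell were Cyp2c55 at -1.68 ± 0.27, Nat8 at -1.47 ± 0.16, the zinc finger genes Zfp979 at -1.32 ± 0.26 and Zfp810 at -1.07 ± 0.18, Pkdcc at -1.02 ± 0.18 and the nucleotide synthesis gene Ctps at -0.89 ± 0.18. The count of 124 was 26 and 44 without control chow 1 or 2 and 22 and 21 without control high-fat 1 or 2. It was 69 without penicillin chow 3, 78 without penicillin high-fat 3 and 303 without penicillin chow 1, and 242 with the 18S signal as a covariate. Of the 20 genes named by size, Cyp1a2, Nat8, Gstm3, 1810053B23Rik, Cyp17a1, Gsta2 and Cyp2b10 passed in each of the 12 fits that left out an array.

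In penicillin mice the diet comparison called 1147 genes, 886 higher and 261 lower, 488 of them by at least 1.5-fold. Cyp2b9 rose by 5.23 ± 0.51, Cidea by 4.36 ± 0.38, Hao2 by 3.27 ± 0.15 and Cidec by 2.59 ± 0.39. Among genes that fell were Hsd3b5 at -3.92 ± 0.50, the glucuronosyltransferase Ugt2b38 at -3.46 ± 0.38 and Lifr at -2.00 ± 0.12, whose other probe sets stood at -0.58 and -0.54. Of 20 lipid droplet and PPAR gamma target genes 11 rose and 1 fell, among them Cd36 by 1.81 ± 0.11, Vldlr by 2.41 ± 0.24 and Mogat1 by 1.89 ± 0.21. The lipase Lipe fell by 0.64. Adjusted over the list alone 14 were higher and 2 lower, and the median was 0.65 (camera adjusted p = 4.04e-09, and adjusted p = 0.00427 with an estimated correlation).

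Of 11 male-biased genes 8 fell in penicillin mice on high-fat diet, or 10 adjusted over the list alone, with Cyp7b1 lower by 1.47 ± 0.11 and the complement gene C6 by 0.97 ± 0.15 (median -0.97, adjusted p = 4.96e-10, and adjusted p = 0.0329 with an estimated correlation). Of 15 female-biased genes 6 rose, or 7 adjusted over the list alone, including Cyp17a1 by 1.72 ± 0.26 and Cyp4a14 by 1.49 ± 0.27 (median 0.63, adjusted p = 9.24e-06, and adjusted p = 0.0329 with an estimated correlation). Of 29 PPAR alpha and fatty acid oxidation genes 12 rose, or 17 adjusted over the list alone. The hepatokine Fgf21 rose by 2.53 ± 0.39, the pyruvate dehydrogenase kinase Pdk4 by 2.52 ± 0.41 and Acot2 by 0.87 ± 0.09 (median 0.35, adjusted p = 4.70e-09, fry adjusted p = 0.00123, and adjusted p = 0.213 with an estimated correlation). Of 31 xenobiotic genes 9 fell and 3 rose, or 11 and 3 adjusted over the list alone, with Cyp1a2 at -1.55 ± 0.09 and the carboxylesterase Ces2a at -1.68 ± 0.19 (median -0.22, adjusted p = 0.00312, fry adjusted p = 0.0272, and adjusted p = 0.474 with an estimated correlation).

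Some markers of macrophages, stellate cells and endothelium rose in penicillin mice on high-fat diet, while the cholangiocyte, neutrophil, T and NK cell and B and plasma cell lists did not pass camera (adjusted p = 0.463, 0.0903, 0.744 and 0.691). Of 21 macrophage and Kupffer cell markers 10 rose, or 14 with 1 lower adjusted over the list alone. Among them were Adgre1 by 1.09 ± 0.20, Cd68 by 1.03 ± 0.19 and Cd5l by 0.95 ± 0.17 (median 0.70, adjusted p = 6.07e-09, fry adjusted p = 0.0146, and adjusted p = 0.331 with an estimated correlation). Of 22 stellate cell and fibrosis genes 8 rose, or 13 adjusted over the list alone. The collagens Col3a1 and Col1a2 rose by 1.57 ± 0.17 and 0.94 ± 0.16 and the proteoglycan Lum by 1.01 ± 0.16 (median 0.44, adjusted p = 6.74e-09, fry adjusted p = 0.00443, and adjusted p = 0.216 with an estimated correlation). Of 15 sinusoidal endothelial markers 5 rose, or 10 adjusted over the list alone, with Lyve1 higher by 1.80 ± 0.34 (median 0.41, adjusted p = 2.46e-06, fry adjusted p = 0.00536, and adjusted p = 0.234 with an estimated correlation). Of 16 cell cycle genes 4 rose, or 7 adjusted over the list alone. Mki67 rose by 0.58 ± 0.10 and the cell cycle inhibitor Cdkn1a by 1.66 ± 0.32 (median 0.23, adjusted p = 8.80e-04, fry adjusted p = 0.00536, and adjusted p = 0.234 with an estimated correlation). The baseline arrays penicillin chow 2 and 3 had a low 18S signal, the lowest macrophage scores, -0.49 and -0.67, and the lowest endothelial scores, -0.33 and -0.37. In the other low-18S array, penicillin high-fat 2, these scores were not low, at 0.28 and 0.12. Without the 3 low-18S arrays the baseline is penicillin chow 1 alone, the mouse with high acute-phase genes, so that fit does not isolate the 18S signal. In it Adgre1: high-fat diet in penicillin mice stood at 0.68, Cd68: high-fat diet in penicillin mice at 0.49, Cd5l: high-fat diet in penicillin mice at 0.48 and Lyve1: high-fat diet in penicillin mice at 0.78, with adjusted p from 0.115 to 0.198. With all arrays and the 18S signal as a covariate the 4 genes kept their calls, at 1.02, 0.93, 0.92 and 1.59. Of 15 hepatocyte markers 1 fell, Cps1 by 0.40 ± 0.08, or 2 adjusted over the list alone.

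Other large rises in penicillin mice were Rad51b by 4.38 ± 0.44, Slc22a29 by 3.45 ± 0.25, Ppp1r3g by 3.30 ± 0.40, Slc22a27 by 3.22 ± 0.17, Rgs16 by 3.11 ± 0.41 and the defensin Defb1 by 2.57 ± 0.29. Among those that fell were Gm16551 at -1.89 ± 0.35, Cyp2c54 at -1.75 ± 0.32, C8b at -1.72 ± 0.17, 3110082I17Rik at -1.67 ± 0.40, Ces2b at -1.67 ± 0.37 and the adhesion molecule Cadm4 at -1.66 ± 0.17. The count of 1147 was 743 without penicillin chow 3 and 530 without penicillin high-fat 1. It was 511 with the clock score as a covariate and 652 without both penicillin chow 1 and penicillin high-fat 1. Of the 20 genes named by size, 18 passed in each of the 12 fits that left out an array; Ces2b lost its call without penicillin chow 3 or penicillin high-fat 1, and 3110082I17Rik without penicillin chow 1 or penicillin high-fat 1 or 3.

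The diet effects in control and penicillin mice correlated across genes at r = 0.663 (Spearman rho = 0.580). They shared 68 genes higher and 17 lower, where lists drawn independently, which calls from 1 fit are not, would share 5.78 and 0.644, and 0 genes were called in opposite directions. These counts do not show that the remaining calls differ between treatments; the interaction, which tests that, called 6 genes.

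**Figure D3:**
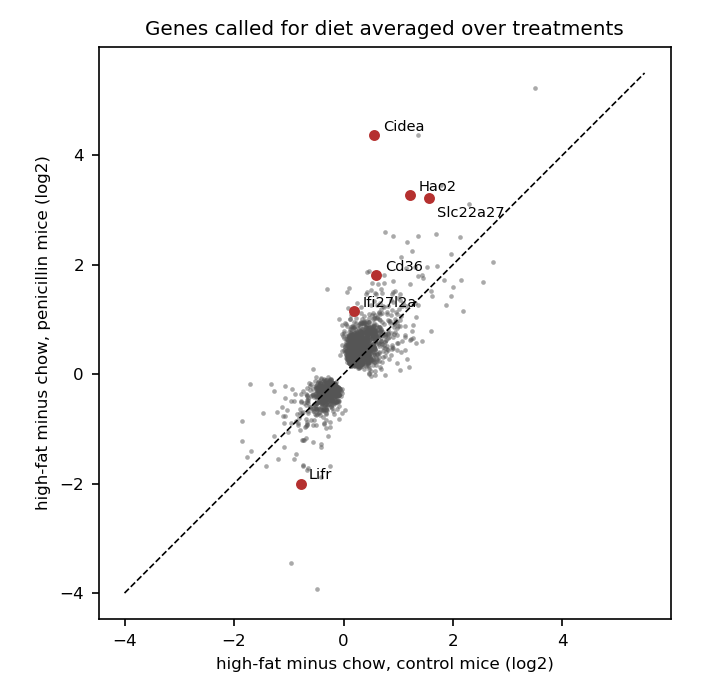
High-fat minus chow difference in penicillin mice (vertical, log2) against that in control mice (horizontal, log2) for the 1997 genes called for diet averaged over treatments; the dashed line marks equal change. Red points are the 6 genes called for the interaction, with Cidea at 4.36 in penicillin mice.

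Averaged over treatments, high-fat diet changed 1997 genes, 1328 higher and 669 lower, with 373 changed by at least 1.5-fold. With the clock score as a covariate the count was 1035, of which 940 were shared. Cyp2b9 rose by 4.37 ± 0.36, Rad51b by 2.87 ± 0.31, Rgs16 by 2.70 ± 0.29, Slc22a29 by 2.61 ± 0.17, Cidea by 2.46 ± 0.27, Slc22a27 by 2.39 ± 0.12, Nipal1 by 2.38 ± 0.30, Apoa4 by 2.32 ± 0.30, Ppp1r3g by 2.27 ± 0.29 and Hao2 by 2.24 ± 0.11. Genes that fell were Hsd3b5 at -2.21 ± 0.35, Cyp2b10 at -1.64 ± 0.16, Ces2b at -1.55 ± 0.26, Cyp2c55 at -1.54 ± 0.19 and asparagine synthetase, Asns, at -1.54 ± 0.32. Lifr at -1.39 ± 0.08, Cyp1a2 at -1.37 ± 0.06, Gsta2 at -1.35 ± 0.17, Serpina9 at -1.22 ± 0.17 and the male-biased fatty acid hydroxylase Cyp4a12a at -1.21 ± 0.19 fell too. Cidea, Slc22a27, Hao2 and Lifr passed the interaction test, so their averages are not read as an effect of the same size in control and penicillin mice. For Hao2 and Lifr the direction was shared. Hao2 was called higher in both kinds of mouse. Lifr fell in penicillin mice, and in control mice it lay at 11.46 to 11.65 on chow and 10.69 to 10.97 on high-fat diet. On high-fat diet Cidea lay at 5.41 to 5.59 in control mice and at 8.14 to 9.79 in penicillin mice. In control mice Hsd3b5 lay at 12.68 to 13.01 on chow and 12.22 to 12.63 on high-fat diet. In penicillin mice it lay at 11.70 to 12.88 and 7.15 to 9.58. The average of Hsd3b5 thus came mostly from penicillin mice, though its interaction did not pass. The other probe sets of Lifr stood at -0.41 and -0.22, and those of Cyp2b10 at -3.03 and -2.88. All 20 passed in each of the 12 fits that left out an array.

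With diet averaged over treatments, 10 of 11 male-biased genes fell, both over all genes and adjusted over the list alone (median -0.84, adjusted p = 3.56e-09, and adjusted p = 0.0465 with an estimated correlation). Of 15 female-biased genes 9 rose and 1 fell by either count (median 0.93, adjusted p = 1.14e-05, and adjusted p = 0.0426 with an estimated correlation). Of 20 lipid droplet genes 11 rose and 1 fell, or 12 and 1 adjusted over the list alone (median 0.45, adjusted p = 3.38e-07, and adjusted p = 0.0113 with an estimated correlation). Of 21 macrophage markers 13 rose, or 17 with 1 lower adjusted over the list alone (median 0.61, adjusted p = 1.09e-08, fry adjusted p = 0.00658, and adjusted p = 0.302 with an estimated correlation). The macrophage, endothelial and stellate scores of the arrays were higher on high-fat diet by 0.51, 0.33 and 0.31 (6 arrays against 6; exact permutation p = 0.00433, 0.00216 and 0.00649; adjusted p = 0.0519 for each). The Gapdh 3′ minus 5′ signal, a sign of RNA integrity, differed by -0.06 (exact permutation p = 0.00866, adjusted p = 0.0519). That of Actb differed in the same direction, by -0.09 (exact permutation p = 0.0195, adjusted p = 0.0935).

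**Figure D4:**
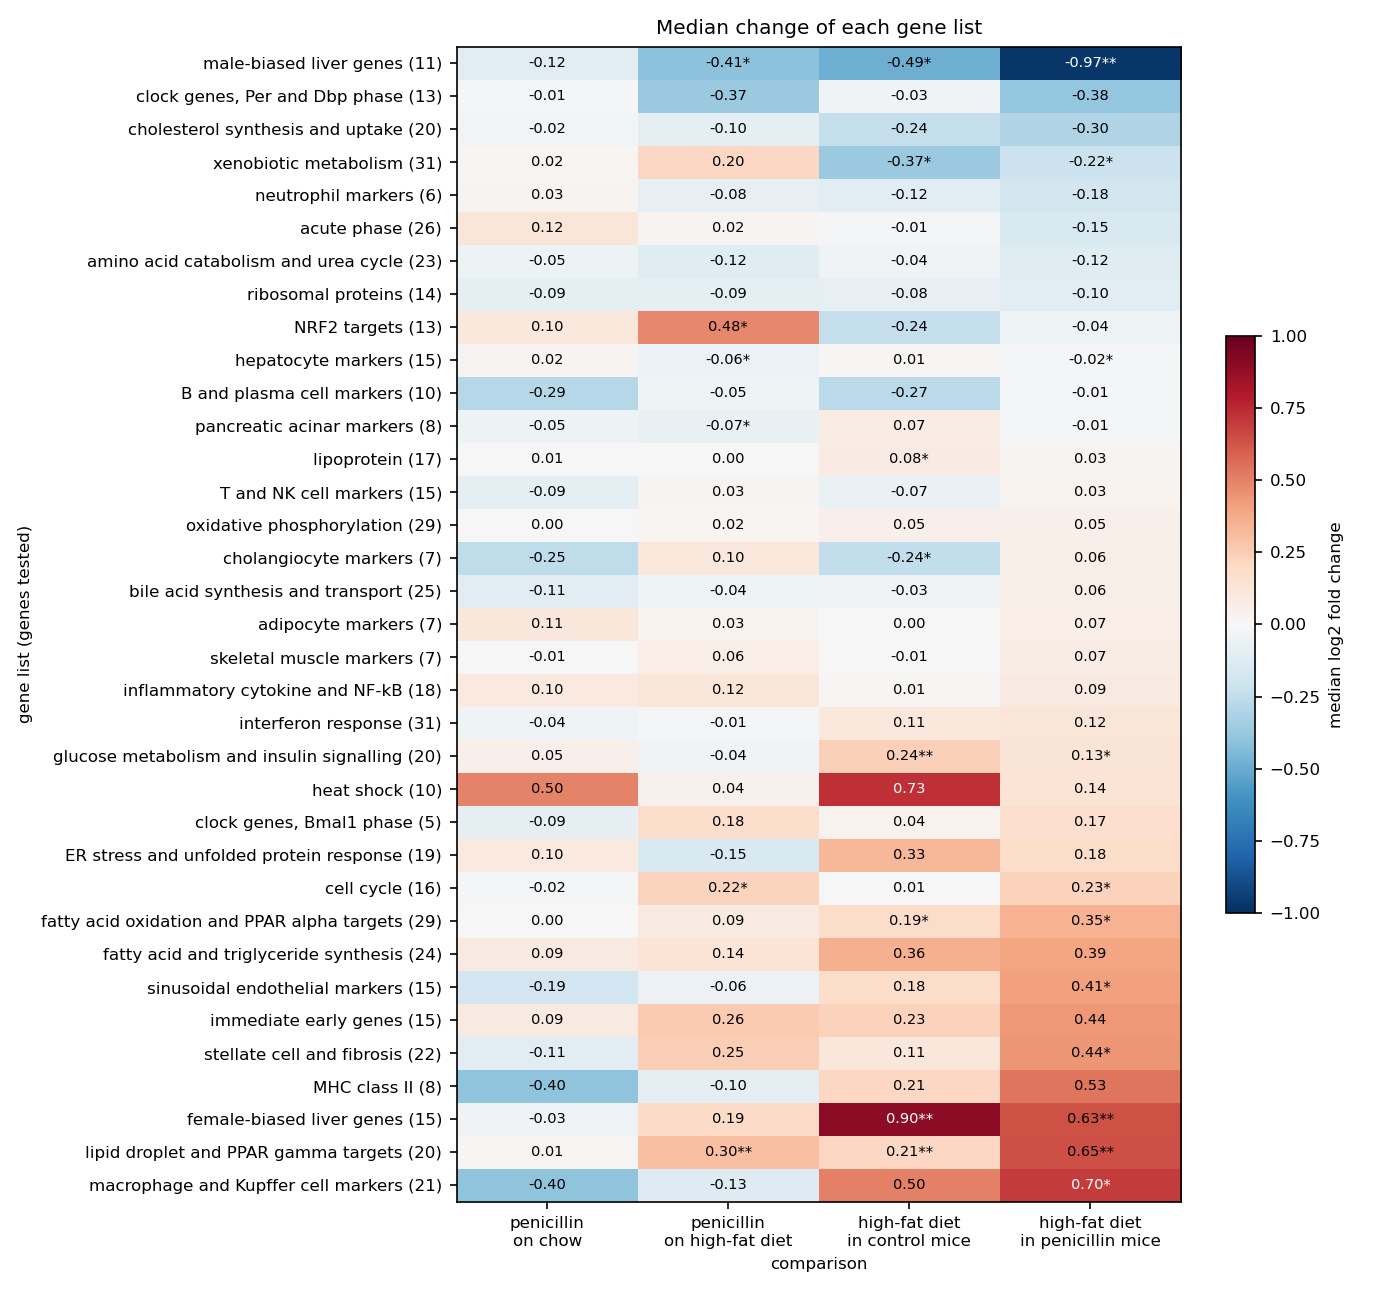
Median log2 change of 35 gene lists in the comparisons of penicillin within each diet and of diet within each treatment, with the number of genes tested in brackets. Colours run from -1 (blue) to 1 (red); 2 asterisks mark an adjusted p under 0.05 by camera with an estimated correlation and 1 asterisk by fry only, and the lipid droplet list carries 2 asterisks in 3 of the comparisons, with 0.65 for high-fat diet in penicillin mice.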

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

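Of the tests in this part, those on hepatocyte markers, neutrophil markers, array quality in 1 mouse, the share of non-hepatocyte cells and the splits inside each diet were chosen only after the results they bear on had been seen. The results named first here stand out because they passed the interaction test of penicillin and diet. Single genes were Hao2 at 2.06, Cd36 at 1.21, Ifi27l2a at 0.97, Cidea at 3.80 and Slc22a27 at 1.66, with Lifr at -1.22 (limma, Benjamini-Hochberg adjusted p under 0.05). Cidea, Hao2 and Slc22a27 lay near the floor of the filter in both chow groups, so for these 3 the test does not show that the penicillin effects differ.

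By camera, 18 lists passed for the interaction. Medians above 0 were those of lipid droplet and PPAR gamma targets at 0.49, cholangiocyte markers at 0.36, MHC class II at 0.33, immediate early genes at 0.32, stellate cell and fibrosis genes at 0.31, cell cycle genes at 0.29, macrophage and Kupffer cell markers at 0.28, NRF2 targets at 0.25, xenobiotic metabolism at 0.22 and sinusoidal endothelial markers at 0.15. Medians below 0 were those of heat shock genes at -0.44, clock genes of the Per and Dbp phase at -0.38, male-biased liver genes at -0.27, ER stress genes at -0.21, acute phase genes at -0.13, glucose metabolism and insulin signalling at -0.13, pancreatic acinar markers at -0.084 and hepatocyte markers at -0.067. With the estimated correlation 1 of the 18 lists passed, lipid droplet and PPAR gamma targets. A signal also stood in data that the comparisons leave aside: of 3621 tested probe sets with no gene symbol, 254 were called for diet averaged over treatments, 137 higher and 117 lower.

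Random regrouping of the arrays was set against each count. For comparisons of 3 against 3 arrays there are 10 splits, too few for a share under 0.05. The real grouping was the 1 split of 10 with as many called genes for penicillin on chow (1, highest other 0), penicillin on high-fat diet (47, highest other 0), diet in control mice (124, highest other 2) and diet in penicillin mice (1147, highest other 1). For lists, the splits with as many calls numbered 4 of 10 for penicillin on chow (11, highest other 14), 3 for penicillin on high-fat diet (12, highest other 13), 1 for diet in control mice (19, highest other 13) and 2 for diet in penicillin mice (18, highest other 19).

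Over 100 splits, 1 had as many called genes for penicillin averaged (20, highest other 10) and 1 for diet averaged (1997, highest other 132). For the interaction 3 of 100 did (6, highest other 680), and the splits with the most calls mix the diets. With arrays regrouped only inside each diet, 9 of 100 had as many as the real 6, and the highest other count was 28. Regrouping inside the diets thus does not set the number of interaction genes apart from chance. List counts were matched by 6 of 100 splits for the interaction (18, highest other 20), 7 for penicillin averaged (15, highest other 21) and 7 for diet averaged (19, highest other 22). The list counts at the preset correlation were thus not set apart from those of regrouped arrays in these 3 contrasts. Regrouped arrays can still carry part of the real group differences, so these shares do not tell what chance alone would give.

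The higher lipid droplet genes and lower male-biased genes of penicillin mice on high-fat diet might reflect the time of collection, RNA quality or a lower share of hepatocytes. With the clock score as a covariate the 47 called genes kept 0.941 of their median change, or 0.805 to 1.01 with 1 array left out, and 34 of them kept their call. With the 18S signal they kept 1.01 of it, or 0.973 to 1.03 with 1 array left out. Of 15 hepatocyte markers 0 fell as far as the median male-biased gene, at -0.41. The clock and 18S shares cover all 47 called genes, not the lipid droplet and male-biased genes alone. Calls favour genes with little spread within groups, and the covariates were fitted on that spread, so shares near 1 were favoured in advance. The shares thus do not exclude time of collection or RNA quality. The hepatocyte markers, the lowest at -0.33, argue against a lower hepatocyte share for the male-biased genes only. Penicillin treatment and any factor such as cage that follows the groups are not told apart here.

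The acute-phase genes of penicillin chow 1 could come from neutrophils in the sample or from the quality of the array. Of 6 neutrophil markers 2 lay above the range of the other arrays, S100a8 at 9.14 and S100a9 at 9.29, and Ngp, Mmp9, Cxcr2 and Elane lay within it. These 4 stayed near the floor of the filter on every array and exclude nothing, so neutrophils stay open. Of 4 quality measures 0 lay outside the range of the others. They give no sign of poor quality, but the others ranged from 11.5 to 13.9 in 18S signal, so array quality is not excluded. A response of that mouse itself, such as an infection or injury, was not tested.

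The lower macrophage markers of penicillin mice on chow may reflect a lower share of all non-hepatocyte cells or RNA quality. The score differed by -0.35 (95% interval -0.72 to 0.01), the endothelial score by -0.22 (-0.41 to -0.04) and the stellate score by -0.16 (-0.37 to 0.05). Macrophage minus stellate was -0.19 (-0.62 to 0.24), and with the 18S covariate the macrophage difference was -0.24 (-0.69 to 0.21). Both explanations stay open, as does an effect of penicillin on the cells.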

How the results depend on the processing

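The covariate fits and the fits without groups of arrays were chosen after the arrays had been seen. Of the named genes 0 reversed under the alternatives that refit each gene, which leave out every probe set on its own and only the 6 arrays compared. A reversal was counted only where the reported or the alternative fit passed the threshold. Changes of direction where neither fit passed were not counted. Other probe sets of the same gene passed the filter for 416 named gene results. Of these, 1 was opposed by another probe set at an unadjusted limma p under 0.05. The lipid droplet list passed under all 26 alternatives, which include camera refits, camera with an estimated correlation and fry, in each of the 6 contrasts it passes, as did female-biased genes in the 3 diet contrasts, male-biased genes for diet in penicillin mice and averaged, and glucose metabolism for diet in control mice. Signal over background limits dim genes, whose changes are compressed. Except where fewer arrays or genes were tested, the cause was not tested.

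Values follow the order penicillin on chow, penicillin on high-fat diet, diet in control mice, diet in penicillin mice, interaction, penicillin averaged and diet averaged. With 1 array left out, genes changed numbered 0 to 4, 21 to 113, 21 to 303, 530 to 1114, 0 to 10, 2 to 93 and 1356 to 2077, and gene lists 7 to 12, 12 to 18, 16 to 19, 15 to 18, 13 to 21, 12 to 19 and 17 to 22. The agreement of effects ranged from 0.145 to 0.247 for penicillin and from 0.606 to 0.671 for diet. At an adjusted p under 0.1 genes changed numbered 2, 118, 386, 1933, 7, 65 and 3050, and at 1.5-fold 488 for diet in penicillin mice and 373 for diet averaged. Gene lists with the estimated correlation numbered 0, 1, 3, 3, 1, 1 and 3, and with fry 0, 6, 8, 11, 3, 2 and 15.

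For penicillin on chow 0 genes changed with the mean of all probe sets, every probe set on its own, arrays centred on the median, or only the 6 arrays compared, 4 with the 18S covariate, 3 with the clock covariate and 2 without the acute-phase and clock outliers. Without the 3 low-18S arrays 251 genes and 7 gene lists changed; that fit holds 1 penicillin mouse on chow, the acute-phase outlier penicillin chow 1, assumed to vary like the other groups, and shares 0 calls with the reported fit. Only the 6 arrays compared gave 482 genes changed: high-fat diet in penicillin mice. Every probe set on its own gave 1 for the interaction, 12 for penicillin averaged and 3136 for diet averaged. Array weights gave 183 for penicillin on high-fat diet, 571 for diet in control mice, 15 for the interaction and 108 for penicillin averaged. The 18S covariate gave 98, 242, 2 and 246 for the same contrasts. The clock covariate gave 511 for diet in penicillin mice, 2 for the interaction and 1035 for diet averaged. Without the 3 low-18S arrays there were 148 for penicillin on high-fat diet, 24 genes and 9 gene lists for the interaction, and 416 for penicillin averaged. Without the outliers there were 27 for penicillin on high-fat diet, 289 for diet in control mice and 652 for diet in penicillin mice. With the filter at the 60th percentile the agreement of effects between strata: penicillin was 0.248; agreement of effects between strata: high-fat diet was 0.690, and 0.634 with no filter.

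Lists that turned direction, counted by the same rule as for genes, follow as list and contrast, with adjusted p under the alternative. Without penicillin_chow replicate 1 these were list acute phase: penicillin on chow (0.265, range with 1 array left out 2.09e-05 to 0.265), list acute phase: high-fat diet in penicillin mice (0.587, 8.04e-04 to 0.587) and list acute phase: interaction of penicillin and diet (0.467, 4.33e-04 to 0.467), and without the outliers the same (0.283, 0.461 and 0.317). Fatty acid and triglyceride synthesis turned for penicillin on chow with the 18S covariate (0.734) and without the low-18S arrays (0.845), and for penicillin averaged over diets without them (0.836). Without penicillin_hfd replicate 3 it was list cholesterol synthesis and uptake: penicillin on high-fat diet (0.00526, 1.51e-04 to 0.773) and list cholesterol synthesis and uptake: interaction of penicillin and diet (0.0110, 6.68e-04 to 0.985). Without the low-18S arrays, where penicillin chow 1 is the only penicillin mouse on chow, these were list bile acid synthesis and transport: high-fat diet in penicillin mice (0.0306), list bile acid synthesis and transport: interaction of penicillin and diet (0.0366), interferon response for high-fat diet in penicillin mice (0.859), list inflammatory cytokine and NF-kB: interaction of penicillin and diet (0.0217), and macrophage and Kupffer cell markers for the same contrast (0.316).

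The replicate block gave 0 genes for penicillin on chow, 70 for diet in control mice, 2 for the interaction and 2 for penicillin averaged. Of 18 pairs of arrays with the same replicate number 3 had a residual correlation above 0.1 (range -0.23 to 0.17), and 2 of 12 arrays correlated best with their own number, so the numbers are not read as a pairing.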

Other observations

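The test of the size of the diet response in this part, with its covariates and left-out arrays, was chosen only after the counts had been seen. Beyond the genes described so far, 3 immediate early genes rose with diet in penicillin mice. The transcription factor Jun rose by 1.46, the phosphatase Dusp1 by 1.36 and the RNA-binding gene Zfp36 by 0.63 on high-fat diet, the 3 of 15 immediate early genes called by limma at a Benjamini-Hochberg adjusted p under 0.05, or 4 adjusted over the list alone (median 0.44, camera adjusted p = 0.0122, and adjusted p = 0.474 with an estimated correlation). Of 31 interferon response genes 4 rose, Ifi27l2a by 1.16, Gbp3 by 0.83, Ifit2 by 0.67 and Trim30a by 0.61, and Stat2 fell by 0.36, the same counts as adjusted over the list alone (camera adjusted p = 0.0453, and adjusted p = 0.659 with an estimated correlation). Of 18 inflammatory cytokine and NF-kB genes 2 rose, the chemokine Cxcl9 by 1.12 and the adhesion molecule Vcam1 by 1.24, by either count, and the list did not pass (camera adjusted p = 0.212). Of 8 genes in the MHC class II list 3 rose, H2-Ab1, H2-DMa and the protease gene Ctss by 0.74, 0.71 and 0.66, or 6 adjusted over the list alone (camera adjusted p = 0.00946, and adjusted p = 0.474 with an estimated correlation). The baseline arrays penicillin chow 2 and 3 had a low 18S signal and low macrophage scores, -0.49 and -0.67. Penicillin high-fat 2, also low in 18S signal, had a macrophage score of 0.28. The iron hormone gene Hamp fell by 0.87.

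Cholesterol synthesis and uptake genes lay lower with high-fat diet averaged over treatments, with 3 of 20 lower, or 4 adjusted over the list alone, and a median of -0.25 (camera adjusted p = 0.00563, and adjusted p = 0.563 with an estimated correlation). Ribosomal protein genes had medians of -0.09 for penicillin on either diet over 14 genes, with 0 called on chow or on high-fat diet (camera adjusted p = 9.98e-04 and 1.20e-04, and adjusted p = 0.660 and 0.327 with an estimated correlation).

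The larger number of genes called for diet in penicillin mice, 1147 against 124, might mean a larger response to diet. Over the 1997 genes called for diet averaged over treatments, the mean change in the direction of that call was 0.367 in control and 0.513 in penicillin mice, a difference of 0.145, and it was larger in penicillin mice for 1475 genes. Relabelling penicillin and control within each diet gave a two-sided permutation p of 0.005 over 400 relabellings, the smallest value possible. The 1997 genes were chosen with the spread inside the real groups and were not chosen anew for each relabelling. That can favour the real grouping, so this p is not exact. The difference was 0.120 without penicillin high-fat 1 and 0.167 without control high-fat 1, its extremes with 1 array left out. It was 0.120 with the clock score and 0.126 with the 18S signal as a covariate, 0.124 without penicillin chow 1 and penicillin high-fat 1, and 0.153 without the 3 low-18S arrays. The count of 1147 itself was 511 with the clock covariate and 652 without those 2 outlying arrays, and penicillin chow 2 and 3 had a low 18S signal. The fits of the difference all use the same 1997 genes, so they share any bias of that choice. Mean macrophage, endothelial and stellate scores were lower in penicillin than in control mice on chow. They stood at -0.43 against -0.08, -0.28 against -0.06 and -0.24 against -0.08. A lower share of such cells on chow, left open above, was not taken into account. A larger diet response in penicillin mice thus stays possible but is not settled. The difference rests on 3 mice per group and on a test that can favour the real grouping and was chosen after the counts were seen.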
